A study of Oryza sativa with 6 samples.

How the data were processed

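Gene expression was measured in total RNA of the 7th leaf blade of rice, 400 ng per labelling, on 6 Agilent 1-colour (Cy3) oligonucleotide arrays, 3 at 7 h and 3 at 13.5 h after CO2 was raised to 1000 ppm. Per the labels, plants grew with 14 h of light and 10 h of dark at 28 and 23 °C. Per the file headers, the authors' scanner output came from Agilent Feature Extraction 11.5.1.1, and its processed signal is a background-corrected and spatially detrended spot intensity on a linear scale, with no normalization between arrays. Signals are printed with 3 significant digits, and outlier flags and well-above-background flags come with each spot. The mean spot intensity and the median local background intensity are deposited beside it. A value table deposited by the authors holds 29525 spots, and comparison with the scanner values showed that each column is a ratio, the processed signal over the array's own 75th percentile, linear, not centred per gene and rounded to 0.01. The medians of its columns were 0.53, 0.53 and 0.52 at 7 h and 0.55, 0.55 and 0.55 at 13.5 h; how its spots were selected is not given in the sources used here. The genome build behind the probes is not given in the sources used here.

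Each array held 43734 non-control spots, of which 42124 named a locus of the Rice Annotation Project. These covered 29690 loci, 7801 of them with more than 1 probe; the remaining 3.68% of spots (microRNA, random, genomic and other probes) stayed out of the gene tests. Gene descriptions are those of the array design and can be old. The gene table given as reference does not pair these loci with its entries, so no coordinates are printed. Gene symbols were written from general knowledge in the fixed lists and kept where the array's description did not contradict them; 160 listed loci were kept, 5 were dropped because their description named another function and 3 were not on the array. Of all listed symbols, those of dropped and absent loci included, the reference gene table (assembly ASM3414082v1) placed 74 on the chromosome that the locus names and 2 (SPS1 and AS2) on another, and 92 were not found in it.

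The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The main values were log2 of the processed signal over the array's 75th percentile of non-control spots. Control spots and outlier-flagged spots were left out, spots of a probe were averaged, and probes were kept if well above background on at least 3 of the 6 arrays (32303 probes). Each locus was represented by the probe with the highest mean over the 6 arrays, which left 22112 genes. Of 6443 genes with more than 1 kept probe, 20 had probes called in both directions. Groups were compared with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are 13.5 h minus 7 h, and their standard errors are limma's moderated ones. A gene with no array of one time well above background is given as a bound ("at least N-fold"): the mean of the bright group against the mean, per array, of the higher of the lowest signal among probes well above background and the probe's own.

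The gene lists (21 pathway lists and 5 lists of other cell types or states), the main tests, the rule for named genes and the first set of alternatives were fixed before the data were examined. Tests and alternatives chosen later are named as such in the closing section. Named genes are the 8 largest rises and 8 largest falls among genes that passed the test, were well above background on all 6 arrays, had non-overlapping groups and had an informative description, all measured clock genes, up to 2 largest rises and 2 largest falls that passed in each other list (or the smallest adjusted p where none passed), and RCA, SPS1, GS2, NIA1, Hd3a and Ghd7 where measured. The rule gave 115 genes, all of which the text prints. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Camera asks whether a list shifts against the other genes; fry asks whether its genes move on balance one way and compares the list with no other genes. None of the 10 lists called with the preset correlation was called with an estimated one.

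Arrays were checked against each other before averaging. Pearson correlations across genes were 0.949 to 0.995 within a time and 0.871 to 0.912 between times. The 13.5 h arrays of replicates 1 and 2 lay on 1 slide and differed least. Over 84 probes printed in duplicate their difference was 0.94 times the spot noise (a ratio of mean squares), and over 25 probes printed 6 to 10 times it was 13.9 times the spot noise, against 2.55 to 12.6 and 21.5 to 193 for the other pairs within a time. Spot noise lies within an array, so these ratios cannot tell 2 hybridisations of 1 RNA from 2 separate samples. The pair was kept as 2 samples because the labels call them different samples, and an alternative that averages them was added. The labels do not say whether the samples of a time came from separate growth runs, so p-values measure the spread between these samples, which can be partly technical. Scan date and slide were read from the headers as batches: scan date 1 held 2 arrays at 7 h and 1 at 13.5 h, and scan date 2 held 1 and 2. Both were tested as blocks, scan date as a fixed term and slide as a random one. Only slide 2 held both times (7 h replicate 2 and 13.5 h replicate 3). Slide 4 held the 13.5 h arrays of replicates 1 and 2, and slides 1 and 3 a single 7 h array each. Slide and time were therefore largely confounded.

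The alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median, the authors' deposited table, no filter or a stricter filter on dim probes, the mean over or the second of a gene's probes, limma with trend and robust, slide, scan date or replicate number as a block, each array left out, other thresholds, other list tests and lists by listed loci only. The steps were tested on simulated arrays with the spread of the real ones over 22112 genes: for the gene comparison, of 100 genes changed 2-fold 14% were called and of 100 changed 4-fold 57%, with 6 false calls (7.79% of calls). Only 200 genes were changed there, against 36.0% of genes called in the data. The Benjamini-Hochberg cutoff depends on that share, so these percentages do not carry over to the real comparison. In the list comparison, a simulated shift of 0.5 log2 in the cytosolic ribosome list was called (camera adjusted p = 4.97e-46) and no other list was called. On the real arrays that list had a median of 0.53, a camera adjusted p of 1.53e-09 and an estimated correlation of 0.69. The simulation therefore cannot tell how specific list calls are where genes move together.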

Results

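Total RNA from the 7th leaf blade of rice (cultivar Nipponbare) was hybridised to 1-colour microarrays after the plants had been moved from 320 to 360 ppm CO2 to 1000 ppm CO2 at the start of a 14 h light period. There were 3 arrays at 7 h of elevated CO2 (early afternoon) and 3 arrays at 13.5 h (shortly before lights off). The labels describe the 3 samples at each time as separate experiments on different samples, so n = 3 per time throughout unless stated. Arrays of plants kept at ambient CO2 were not analysed here, so time under elevated CO2 and time of day changed together and cannot be told apart. The question that the 6 arrays answer is which transcripts differed between the 2 sampling times under elevated CO2. The 75th percentile of spot brightness was 1140, 1020 and 1160 on the 7 h arrays and 2190, 2470 and 1490 on the 13.5 h arrays. Between 67.4% and 81.0% of the non-control spots of an array were well above background, and no spot was saturated. The small number of arrays limits the precision of every comparison.

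The leaf transcriptome at 13.5 h differed widely from that at 7 h. Among the clock genes, the evening-complex gene OsLUX was 373-fold higher and the morning gene OsLHY was 28.5-fold lower at 13.5 h. A beta-amylase gene (Os10g0565200), whose product releases maltose from starch, was 256-fold higher. The chlorophyll synthesis genes PORA and CAO1 were 16.1-fold and 16.3-fold lower, and 12 of 18 light harvesting genes and 12 of 22 Calvin cycle genes were lower with none higher. Of 156 cytosolic ribosomal protein genes 41 were higher and 1 was lower. Of 22112 genes tested, 7954 changed at an adjusted p under 0.05 (limma, two-sided, Benjamini-Hochberg). Of these, 4156 were higher and 3798 lower at 13.5 h, and 5066 changed at least 2-fold (2648 higher, 2418 lower). In 52.9% of the genes all 3 arrays of one time lay above all 3 of the other, against 10% by chance.

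The balance of rises and falls depended on how arrays were scaled: 52.3% of called genes were higher in the main processing, 39.5% with scaling to the median and 30.5% with normexp background correction, which moved the median log2 change of all genes from 0.04 to -0.13 and -0.26. Both scan dates held both times: with scan date as a block 10218 genes were called, and within scan dates 1 and 2 alone 4246 and 12621 were called. In each date 1 of the times had a single array, and in scan date 2 the whole spread came from the 13.5 h arrays of replicates 1 and 2, so these counts carry little weight. Those 2 arrays shared a slide and correlated at r = 0.995 across genes, the highest of all pairs. The labels call them different samples, but these data do not settle whether they were 2 hybridisations of 1 RNA. With these 2 arrays averaged and counted as 1 sample 3969 genes were called. The count was also 3960 without the 13.5 h array of replicate 1, 3871 without that of replicate 2 and 4404 without the 7 h array of replicate 2. Of 109 genes named by rule that passed the test, 108 kept their call with scan date as a block, 89 under all 3 other scalings, 81 with the pair of arrays averaged and 77 with each array left out in turn. Every call given below as lost when the pair was averaged was also lost with at least 1 array left out.

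Clock genes moved in opposite directions. Of 15 measured clock genes, 4 rose, 5 fell and 6 did not pass, with the same counts when adjusted over the list alone. OsLUX rose by a log2 change of 8.54 (SE 0.54, adjusted p = 0.000582), from a mean normalised log2 signal of -3.84 at 7 h (-2.58, -4.36 and -4.58 on the 3 arrays) to 4.70 at 13.5 h (4.51, 4.60 and 4.99). OsELF3-2 rose by 3.78 (SE 0.40), OsFKF1, a blue-light receptor, by 2.37 (SE 0.48) and OsPRR1, the rice counterpart of TOC1, by 1.92 (SE 0.49). OsLHY fell by 4.83 (SE 0.17, adjusted p = 0.000246), from 4.50 ± 0.14 (SD, n = 3) to -0.33 ± 0.23, and OsRVE8 fell by 4.33 (SE 0.42). The pseudo-response regulator genes OsPRR73, OsPRR37 and OsPRR95 fell by 1.73, 1.57 and 1.32 (SE 0.15, 0.32 and 0.18). OsGI, OsZTL1, OsZTL2, OsPRR59, OsELF3-1 and OsELF4a had log2 changes of 0.00, 0.04, 0.44, 0.35, -0.43 and -0.67 and did not pass, with adjusted p between 0.160 and 0.994. The calls for OsPRR1 and OsPRR37 were lost when the pair of 13.5 h arrays was averaged, and that for OsFKF1 without the 7 h or the 13.5 h array of replicate 2. As a list the clock genes were not called against other genes (median 0.00, mean 0.17, camera downward, adjusted p = 0.614), while fry, which compares the list with no other genes, called them as lower (adjusted p = 0.00939).

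**Figure D1:**
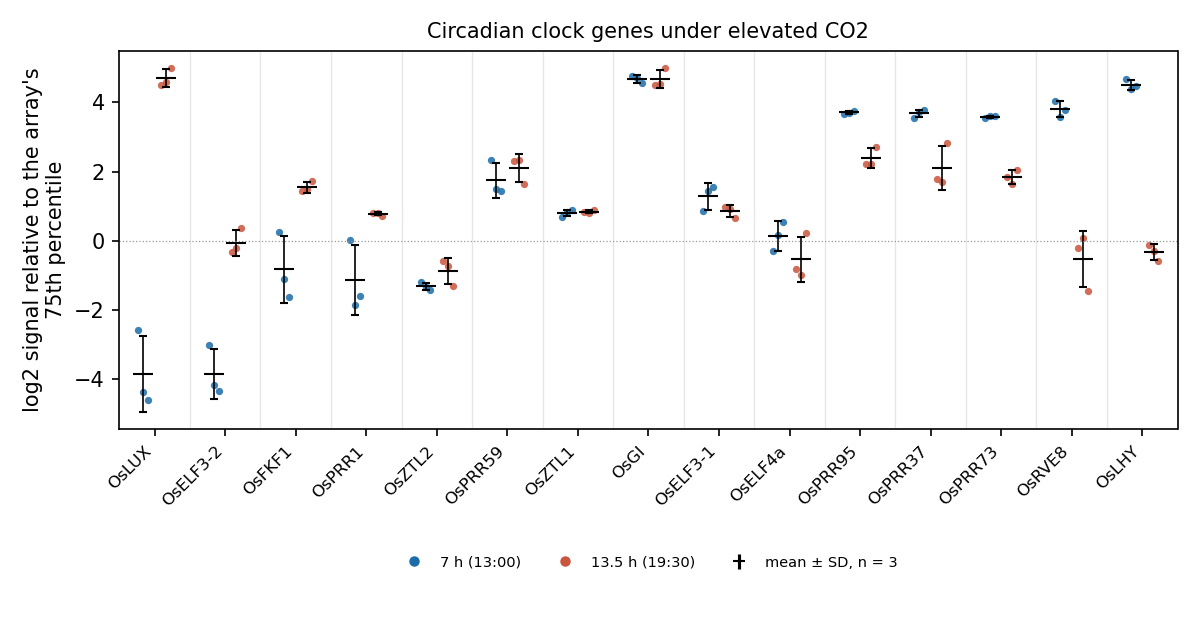
Normalised log2 signal (log2 of the spot signal over the array's 75th percentile) of the 15 clock genes, ordered by their log2 change. Points are single arrays at 7 h and at 13.5 h, and bars give the mean and SD (n = 3); OsLUX and OsELF3-2 lie higher at 13.5 h and OsRVE8 and OsLHY lower, while OsGI lies at the same level at both times.

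Among 13 photoperiodic flowering and photoreceptor genes, 2 rose, 3 fell and 8 did not pass (the same adjusted over the list alone). Hd1, the rice CONSTANS gene, rose by a log2 change of 5.14 (SE 0.87, adjusted p = 0.00799). Only 1 of its 3 arrays at 7 h was well above background, and the change was 7.36 and 2.98 within scan dates 1 and 2. OsCO3 fell by 4.17 (SE 0.24) and OsDof12 by 2.23 (SE 0.38). The phytochrome gene PHYA was higher by 0.49 (SE 0.15, adjusted p = 0.0471), a call lost when the pair of 13.5 h arrays was averaged, with scaling to the median, with no filter on dim probes, with the replicate block, within each scan date and without any of 5 of the 6 arrays. Hd3a did not pass the filter on dim probes. The median of the list was -0.19 and it was not called by camera (adjusted p = 0.318) but was called as lower by fry (adjusted p = 0.0222).

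The largest rises among genes bright on all 6 arrays also took in a heat shock transcription factor gene (Os01g0733200, log2 change 5.71, SE 0.19), a protein kinase gene (Os12g0586100, 5.22, SE 0.18) and a CONSTANS-type zinc finger gene (Os02g0724000, 4.69, SE 0.26). A ferritin-like gene (Os05g0447700), a Myb gene (Os02g0114800) and a peroxidase gene (Os01g0270300) rose by 5.12, 5.06 and 5.04 with wider errors (SE 1.18, 0.84 and 0.91). The call for Os05g0447700 was lost when the pair of 13.5 h arrays was averaged. The largest falls were those of an isocitrate lyase family gene (Os12g0189300, log2 change -7.78, SE 0.28), a CCCH-type zinc finger gene (Os08g0126700, -7.02, SE 0.46) and a glycoside hydrolase family 1 gene (Os11g0683500, -5.93, SE 0.30). A phosphoenolpyruvate translocator gene (Os05g0170900), which carries phosphoenolpyruvate across the plastid envelope, fell by 5.82 (SE 0.13, adjusted p = 0.000190). Genes for a protein described as cytochrome b-245 heavy chain family (Os04g0444800), a bHLH protein (Os03g0782500), a CBS domain protein (Os02g0818000) and a pyruvate dehydrogenase kinase (Os07g0637300) fell by 5.65, 5.57, 5.56 and 5.40.

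Light harvesting, Calvin cycle and photosystem genes were called lower more often than higher at 13.5 h. Light harvesting genes, most of which encode chlorophyll-binding antenna proteins (3 encode photosystem I subunits described as light-harvesting complex I proteins), had a median log2 change of -0.73, with 0 higher, 12 lower and 6 not passing (0 and 12 adjusted over the list alone; camera adjusted p = 2.83e-05, adjusted p = 0.560 with an estimated correlation). The largest falls were those of a type III chlorophyll a/b-binding protein gene (Os07g0562700, -1.75, SE 0.13) and of the Lhca5 gene (Os02g0764500, -1.46, SE 0.18). The Calvin cycle list had a median of -0.57, with 0 higher, 12 lower and 10 not passing (14 lower adjusted over the list alone; camera adjusted p = 8.13e-05, adjusted p = 0.560 with an estimated correlation). A gene described only as phosphoribulokinase/uridine kinase family (Os02g0708200) fell by 1.44 (SE 0.16) and the plastid aldolase gene FBA-cp by 1.09 (SE 0.17). RCA, which encodes Rubisco activase, was lower by a log2 change of -0.60 (SE 0.18, adjusted p = 0.0456), a call lost without any 1 of the 6 arrays, when the pair of 13.5 h arrays was averaged, with quantile normalization, with no filter on dim probes, with the replicate block and within scan date 1. With quantile normalization the light harvesting and Calvin cycle lists had a median of -0.16 each and were not called (adjusted p = 0.298 and 0.224). The medians within scan dates 1 and 2 were -0.74 and -0.80 for light harvesting and -0.68 and -0.67 for the Calvin cycle, and -0.75 and -0.69 with scan date as a block.

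The photosystem and electron transport list had 8 genes higher, 19 lower and 21 not passing, the same adjusted over the list alone (median -0.42, camera adjusted p = 0.0142, adjusted p = 0.644 with an estimated correlation). The list held 18 tested plastocyanin-like genes (5 higher, 4 lower, 9 not passing), so its counts and median do not describe photosystem genes alone. Both genes for photosystem I subunit N among its leading members fell, Os05g0242400 by 2.48 (SE 0.15) and Os12g0189400 by 2.07 (SE 0.20). A PsbQ family gene of the oxygen-evolving complex (Os02g0578400) rose by 3.40 (SE 0.56). A plastocyanin-like gene (Os07g0112700), whose family is not confined to photosynthesis, was at least 3.56-fold higher at 13.5 h (adjusted p = 0.00120), since no 7 h array was well above background; with normexp it was -0.15 and did not pass. The list's medians within scan dates 1 and 2 were -0.56 and -0.49 (-0.53 with scan date as a block). Its call was lost with normexp, with quantile normalization and within scan date 2. Of 26 photorespiration genes 4 rose, 4 fell and 18 did not pass (the same adjusted over the list alone; median -0.19, camera adjusted p = 0.509). GDCP1, for the P protein of glycine decarboxylase, fell by 1.72 (SE 0.27) and a glycine decarboxylase H-protein gene (Os06g0667600) was higher by 1.28 (SE 0.28), the latter call being lost when the pair of 13.5 h arrays was averaged and with normexp. A phosphoglycerate kinase family gene (Os10g0442100), an enzyme of glycolysis and the Calvin cycle rather than of photorespiration, was higher by 1.42 (SE 0.15; call lost with normexp). SHM1, the mitochondrial serine hydroxymethyltransferase gene, was lower by a log2 change of -0.83 (SE 0.22; call lost when the pair was averaged and with quantile normalization).

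Chlorophyll synthesis genes had 4 members higher, 10 lower and 4 not passing, the same adjusted over the list alone (median -0.90, camera adjusted p = 0.0109, adjusted p = 0.560 with an estimated correlation). CAO1, which makes chlorophyll b, fell by 4.03 (SE 0.20, adjusted p = 0.000414). PORA, the light-dependent protochlorophyllide reductase gene, fell by 4.01 (SE 0.60), from 4.73 ± 1.24 (SD, n = 3) to 0.73 ± 0.12. The size of its fall varied, with log2 changes of -4.72 and -2.58 within scan dates 1 and 2. CHLG, the chlorophyll synthase gene, rose by 1.79 (SE 0.37; call lost without the 7 h array of replicate 2) and a coproporphyrinogen oxidase-like gene (Os12g0270100) by 1.49 (SE 0.19). The list's medians within scan dates 1 and 2 were -1.09 and -1.16, and -1.01 with scan date as a block. Its call was lost with normexp, with quantile normalization and within scan date 2 alone.

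**Figure D2:**
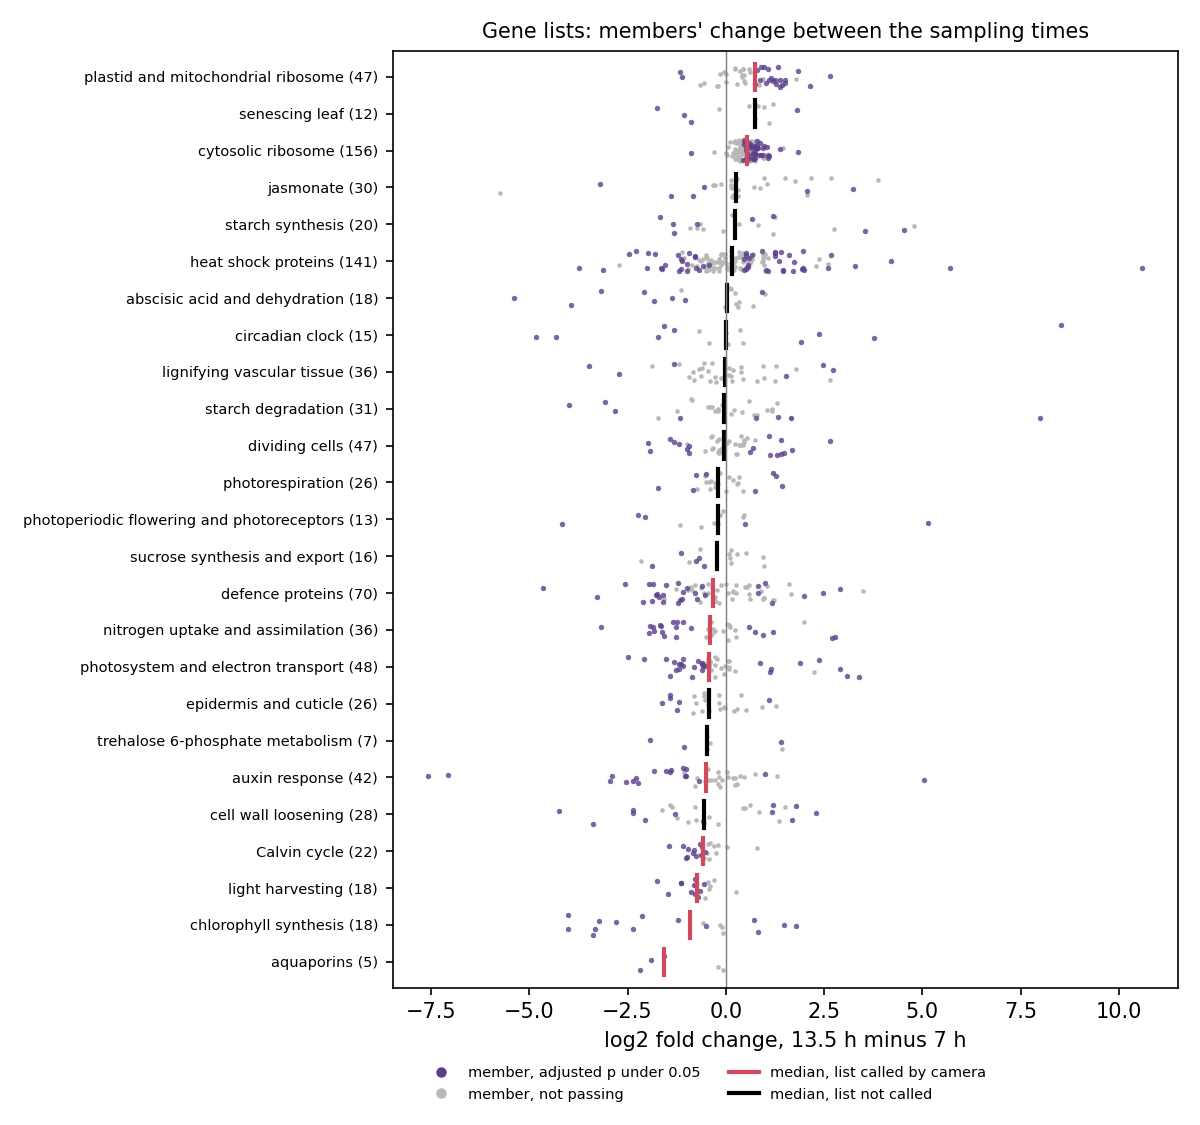
Log2 fold change (13.5 h minus 7 h) of each tested member of the 25 gene lists with at least 5 tested members (number of tested members in brackets), ordered by the list's median; dark points passed the test and grey ones did not. Red bars mark the medians of the 10 lists called by camera with a preset correlation, from aquaporins at -1.58 to plastid and mitochondrial ribosome at 0.74; black bars mark the other medians.

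The starch synthesis and starch degradation lists held genes that moved in both directions. Of 31 genes in the starch degradation list 4 rose, 4 fell and 23 did not pass, the same adjusted over the list alone (median -0.04, mean 0.10, camera adjusted p = 0.836). Its largest rise was that of the beta-amylase gene Os10g0565200, 256-fold (adjusted p = 0.000538), with the log2 signal going from -4.57 ± 0.88 (SD, n = 3) to 3.43 ± 0.45. The other leading members of this list (Os08g0546300 with 1.66, Os03g0801200 with -3.08 and Os10g0552600, 15.9-fold lower with 2 of 3 arrays at 13.5 h above background) encode lipid transfer or amylase inhibitor domain proteins rather than degrading enzymes. Their calls were lost when the pair of 13.5 h arrays was averaged. The starch degradation list held 15 tested genes described as lipid transfer, seed storage or amylase inhibitor domain proteins (1 higher, 3 lower, 11 not passing). Its counts and median therefore do not describe degrading enzymes alone. Of 20 starch synthesis genes 4 rose, 4 fell and 12 did not pass (4 and 6 adjusted over the list alone). The list's median was 0.24 and its mean 0.66, while camera gave the downward direction without a call (adjusted p = 0.905). The starch synthesis median reversed to -0.11 and -0.12 within scan dates 1 and 2 and to -0.20 with scan date as a block. ISA1, a starch debranching isoamylase gene, rose by 4.53 (SE 0.87; 2 of 3 arrays at 7 h were well above background) and the starch synthase gene SSIIb fell by 1.68 (SE 0.24). SSIIa, above background on 1 of 3 arrays at 7 h, was higher by 3.55 (SE 0.86) and GBSSII fell by 1.35 (SE 0.27). The call for SSIIa was lost when the pair of 13.5 h arrays was averaged and with normexp, and that for GBSSII without the 13.5 h array of replicate 2 and with other probe rules.

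None of 16 sucrose synthesis and export genes rose, 5 fell and 11 did not pass (4 fell adjusted over the list alone; median -0.24, camera adjusted p = 0.284; called as lower by fry, adjusted p = 0.0168). The sucrose phosphate synthase genes Os01g0919400 (listed as SPS1, a symbol that the reference gene table places on another chromosome) and Os06g0643800 fell by 1.13 (SE 0.17) and 1.88 (SE 0.19). Of 7 trehalose 6-phosphate genes 1 rose and 2 fell, the same adjusted over the list alone (median -0.47, camera adjusted p = 0.363; called as lower by fry, adjusted p = 0.00939). The trehalose phosphate phosphatase genes Os03g0386500 and Os08g0409100 fell by 1.93 (SE 0.31; 2 of 3 arrays at 13.5 h above background) and 1.06 (SE 0.15). TPS1 was higher by 1.40 (SE 0.39), a call lost when the pair of 13.5 h arrays was averaged and with normexp.

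Nitrogen uptake and assimilation genes were lower in larger number than higher: 6 rose, 15 fell and 15 did not pass, the same adjusted over the list alone (median -0.40, camera adjusted p = 0.0284, adjusted p = 0.560 with an estimated correlation). NIA1, which encodes nitrate reductase, fell by 1.93 (SE 0.22, adjusted p = 0.00246). GS2, the plastid glutamine synthetase gene, fell by 1.28 (SE 0.19), GS1;1 by 1.96 (SE 0.14) and the ammonium transporter gene AMT1;1 by 3.18 (SE 0.34). With quantile normalization the call for GS2 was lost. A further ammonium transporter gene (Os02g0550800) and one described as symbiotic ammonium transporter (Os09g0455300) were higher by 2.79 (SE 0.85; 2 of 3 arrays at 7 h above background) and 2.71 (SE 0.64), calls that were lost when the pair of 13.5 h arrays was averaged and with normexp (for Os02g0550800 also with each other scaling and with scan date as a block). The list's medians within scan dates 1 and 2 were -0.25 and -0.56 (-0.38 with scan date as a block). Its call was lost within each scan date, with normexp, with quantile normalization, with scaling to the median and with no filter on dim probes.

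**Figure D3:**
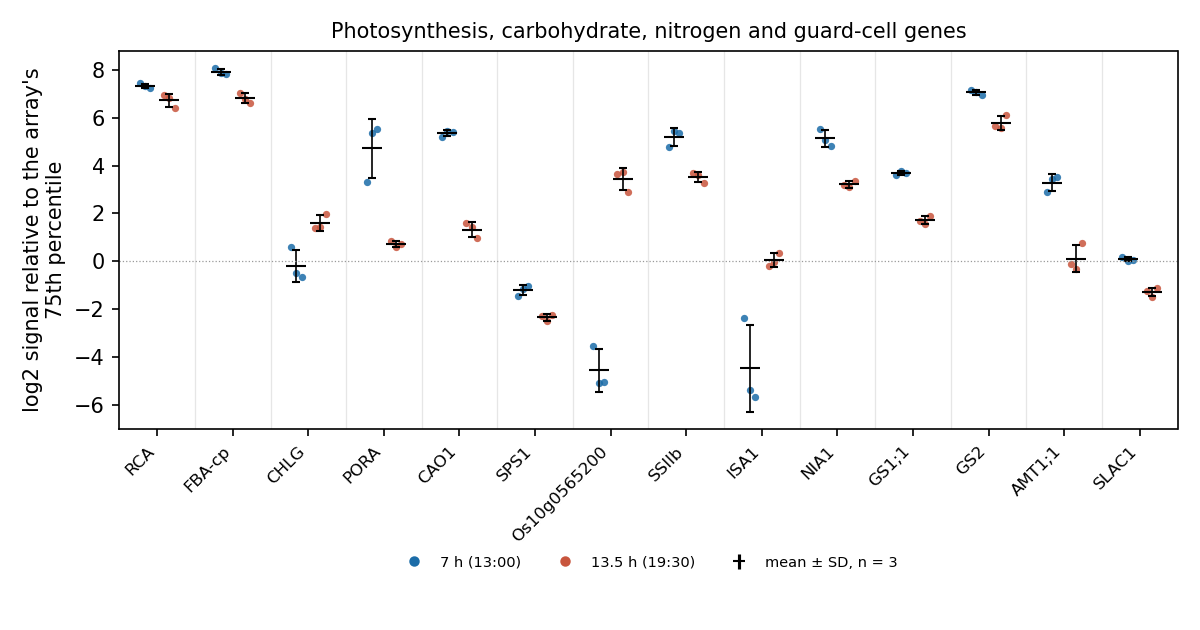
Normalised log2 signal (log2 of the spot signal over the array's 75th percentile) of 14 genes of photosynthesis, chlorophyll synthesis, sugars, starch, nitrogen and guard cells at 7 h and at 13.5 h, with single arrays as points and mean and SD as bars (n = 3). The beta-amylase gene Os10g0565200 rises from -4.57 to 3.43, while CAO1, PORA, NIA1, GS1;1 and AMT1;1 lie lower at 13.5 h on all 3 arrays.

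More ribosomal protein genes were called higher than lower, though most cytosolic ones did not pass. Of 156 cytosolic ribosomal protein genes 41 rose, 1 fell and 114 did not pass, and none passed when adjusted over the list alone (median 0.53, camera adjusted p = 1.53e-09, adjusted p = 0.663 with an estimated correlation of 0.69; the call was also lost with fry, adjusted p = 0.0630). The largest rises, those of 60S acidic protein P0 (Os11g0135400, 1.83, SE 0.52) and 60S protein L15 (Os06g0308200, 1.37, SE 0.32; 2 of 3 arrays at 7 h above background), lost their calls when the pair of 13.5 h arrays was averaged and with normexp. The member that fell (Os12g0524700, -0.89, SE 0.20) is described as mitochondrial ribosomal protein L16, and its call was lost when the pair was averaged and with other probe rules. Of 47 plastid and mitochondrial ribosomal protein genes 21 rose, 2 fell and 24 did not pass (23 and 2 adjusted over the list alone; median 0.74, camera adjusted p = 0.000125, adjusted p = 0.644 with an estimated correlation). The gene of plastid-specific 30S protein 2 (Os09g0279500) was higher by 2.65 (SE 0.55; call lost when the pair was averaged) and a 50S protein L17 gene (Os01g0839300) rose by 2.15 (SE 0.34), while plastid 50S protein L12 (Os01g0662300) and 30S protein S21 (Os02g0189000) genes fell by 1.13 (SE 0.21) and 1.15 (SE 0.13). Within scan dates 1 and 2 the medians were 0.56 and 0.28 for the cytosolic list (0.40 with scan date as a block) and 0.91 and 0.47 for the organelle list (0.64).

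Of 141 genes with a heat shock description 32 rose, 24 fell and 85 did not pass (33 and 24 adjusted over the list alone; median 0.15, camera adjusted p = 0.768). A DnaJ family gene (Os04g0675400), a co-chaperone, had the largest log2 change of the named genes at 10.59 (SE 1.05, adjusted p = 0.00171), with 1 of 3 arrays at 7 h well above background. Its size is therefore uncertain, and was 11.74 and 8.14 within scan dates 1 and 2. The heat shock factor gene Os03g0161900 fell by 3.73 (SE 0.22) and the DnaJ gene Os11g0216100 by 3.12 (SE 0.20).

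The aquaporin, auxin response and defence lists were called lower by camera with the preset correlation, and none of them with an estimated correlation (adjusted p = 0.560, 0.560 and 0.644). Of 5 tested aquaporin genes, which encode water channels, 3 fell, 0 rose and 2 did not pass, the same adjusted over the list alone (median -1.58, camera adjusted p = 0.0284, adjusted p = 0.560 with an estimated correlation). Os07g0448200 fell by 2.18 (SE 0.29) and Os02g0666200 by 1.90 (SE 0.17). The aquaporin medians within scan dates 1 and 2 were -1.50 and -1.70 (-1.60 with scan date as a block). The list call was lost with normexp, with quantile normalization, within scan date 2, without the 7 h array of replicate 1 and without the 13.5 h array of replicate 3. Of 42 auxin response genes 2 rose, 17 fell and 23 did not pass, the same adjusted over the list alone (median -0.50, camera adjusted p = 0.00272, adjusted p = 0.560 with an estimated correlation). An auxin-induced gene (Os09g0546900) was at least 39.6-fold higher at 7 h (adjusted p = 0.00109), since no 13.5 h array was well above background. A SAUR gene (Os09g0546000), above background on 2 of 3 arrays at 13.5 h, fell by 7.06 (SE 0.36), and another SAUR gene (Os12g0626200) was at least 7.77-fold higher at 13.5 h (adjusted p = 0.000570). An AUX/IAA gene (Os06g0335500) was higher by 0.99 (SE 0.21), a call lost when the pair of 13.5 h arrays was averaged. The auxin medians within scan dates 1 and 2 were -0.68 and -0.49 (-0.45 with scan date as a block).

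Of 70 genes in the defence protein list 7 rose, 23 fell and 40 did not pass (9 and 24 adjusted over the list alone; median -0.32, camera adjusted p = 0.0450, adjusted p = 0.644 with an estimated correlation). The list held 26 tested genes described as pathogenesis-related transcriptional factor and ERF (3 higher, 9 lower, 14 not passing), so its counts do not describe defence proteins alone. A PR-1a type gene (Os02g0786900) fell by 4.65 (SE 0.33) and a chitinase gene (Os02g0605900) by 3.27 (SE 0.54), each above background on 2 of 3 arrays at 13.5 h. A gene of the ERF family (Os04g0550200), transcription factors rather than defence proteins, rose by 2.46 (SE 0.34). A thaumatin-like gene (Os03g0244200) was higher by 2.91 (SE 0.62, adjusted p = 0.0162), a call lost when the pair of 13.5 h arrays was averaged. The defence list's medians within scan dates 1 and 2 were -0.61 and -0.49 (-0.56 with scan date as a block). Its call was lost with normexp, with quantile normalization, with scaling to the median, with the authors' table and with the stricter filter. It was also lost with the replicate block, with fry, with members of other function left out, within scan date 2, without the 7 h array of replicate 1 and without the 13.5 h array of replicate 3.

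Abscisic acid and dehydration, jasmonate and cell wall loosening genes were not called as lists in the main processing. Of 18 abscisic acid and dehydration genes 1 rose, 7 fell and 10 did not pass, the same adjusted over the list alone; the median was 0.04 and the mean -0.89 (camera downward, adjusted p = 0.318). Within scan dates 1 and 2 the median was -0.86 and -0.65, and -0.63 with scan date as a block, and within scan date 1 the list was called as lower (adjusted p = 0.0245). That call rests on a single 13.5 h array, whose list median of -0.76 lay apart from the 0.05 and 0.30 of the other 2. A late embryogenesis abundant protein gene (Os01g0314800) fell by 3.94 (SE 0.50) and another (Os02g0250600) was at least 10.3-fold higher at 7 h (adjusted p = 0.00880). The member that was higher at 13.5 h (Os05g0584200, described as Lea14-A, 0.92, SE 0.17) lost its call when the pair of 13.5 h arrays was averaged. Of 30 jasmonate genes 2 rose, 4 fell and 24 did not pass, the same adjusted over the list alone (median 0.25, camera upward, fry downward, camera adjusted p = 0.712). Lipoxygenase genes, whose products start jasmonate synthesis, went both ways: Os02g0194700 fell by 3.20 (SE 0.16), while Os08g0508800 was higher by 3.23 (SE 0.71, adjusted p = 0.0178) and Os03g0700400 by 2.07 (SE 0.51; 1 of 3 arrays at 7 h above background). The calls for Os08g0508800 and Os03g0700400 were lost when the pair of 13.5 h arrays was averaged, and Os03g0700400 was -0.14 with normexp. A ZIM domain gene (Os09g0401300) fell by 1.39 (SE 0.34), a call lost without any 1 of the 7 h arrays and without the 13.5 h array of replicate 1. Of 28 cell wall loosening genes 5 rose, 7 fell and 16 did not pass (7 and 7 adjusted over the list alone; median -0.56, camera adjusted p = 0.318). An expansin gene (Os06g0725300) fell by 3.37 (SE 0.27). OsEXPA4 (Os05g0477600) was lower by a log2 change of -4.23 (SE 1.27; 2 of 3 arrays at 13.5 h above background) and a xyloglucan endotransglycosylase-like gene (Os07g0529700) was 4.93-fold higher (adjusted p = 0.0375), calls lost when the pair of 13.5 h arrays was averaged and with no filter on dim probes. The expansin gene OsEXPA5 (Os02g0744200) was at least 2.21-fold higher at 13.5 h (adjusted p = 0.0180), but its log2 change was -0.49 with normexp. That call was also lost when the pair of 13.5 h arrays was averaged and without the 13.5 h array of replicate 1 or 2.

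None of the lists that mark other cell types or states was called in the main processing. Among 47 dividing cell genes 10 rose, 8 fell and 29 did not pass (11 and 8 adjusted over the list alone; median -0.05, mean 0.07, camera adjusted p = 0.878). Its median was 0.20 and 0.14 within scan dates 1 and 2 and 0.04 with scan date as a block. Histone genes led in both directions, with H3.2 (Os05g0489800) higher by 2.64 (SE 0.31; 1 of 3 arrays at 7 h above background; -0.19 with normexp) and H1 (Os03g0799000) lower by a log2 change of -1.97 (SE 0.25). A histone H2A gene (Os10g0418000) was higher by 1.69 (SE 0.17; 2 of 3 arrays at 7 h above background; call lost with normexp) and histone H4 (Os07g0549900) fell by 1.94 (SE 0.20). For lignifying vascular tissue 3 of 36 genes rose and 3 fell (the same adjusted over the list alone; median -0.02, mean 0.02, camera adjusted p = 0.712). A cinnamoyl-CoA reductase gene (Os09g0419200) fell by 3.47 (SE 0.25) and a 4-coumarate-CoA ligase-like gene (Os04g0683700) by 2.72 (SE 0.49). The caffeoyl-CoA methyltransferase genes Os08g0498400 and Os08g0498600 were higher by 2.72 (SE 0.42, 2 arrays with a value at 7 h) and 2.47 (SE 0.56; 1 of 3 arrays at 7 h above background). The call for Os08g0498600 was lost when the pair was averaged and with normexp. The epidermis and cuticle list had 1 higher and 5 lower of 26 genes (0 and 5 adjusted over the list alone; median -0.43, camera adjusted p = 0.122), with the lipid transfer protein gene Os03g0804200 lower by a log2 change of -1.62 (SE 0.21). Os12g0115300 of the same family was lower by a log2 change of -1.41 (SE 0.22). The LTP 1 gene Os05g0477900 was 2.14-fold higher (adjusted p = 0.0447), a call lost when the pair was averaged and with scaling to the median. The epidermis list was called, as lower, with the second brightest probe (adjusted p = 0.0471), without the 7 h array of replicate 3 (0.0353) and without the 13.5 h array of replicate 1 (0.0365). In the senescing leaf list 1 of 12 genes rose and 3 fell (the same adjusted over the list alone; median 0.74, but -0.14 within scan date 1, 0.52 within scan date 2 and 0.56 with scan date as a block; camera adjusted p = 0.712). NYC1, which starts chlorophyll b breakdown, rose by 1.80 (SE 0.24), while the senescence-associated protein 15 genes Os06g0262800 and Os03g0245700 fell by 1.74 (SE 0.31) and 1.06 (SE 0.20). Of the guard cell list 2 genes were tested, too few for a list test, and the anion channel gene SLAC1 fell by 1.37 (SE 0.15).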

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

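The tests of scan date and of scaling, and the regrouping of arrays for the gene count, were chosen after the result was seen. For the light harvesting, Calvin cycle and ribosomal lists the brightness-matched test was fixed before its own outcome was seen. That an incomplete match leaves it open was added after. No prediction was set for the photosystem and chlorophyll synthesis lists, so their percentiles were read without one. Probes outside the gene comparison carried signal: 83 of 510 microRNA probes were well above background on all 6 arrays, as were 0 of 12 random-sequence and 1 of 24 genomic probes, which are too few to compare with. On at least 3 arrays the shares were 25.3%, 16.7% and 16.7%. Of the 129 microRNA probes kept, 22 changed (1 higher, 21 lower at 13.5 h, limma adjusted p), but the median of the random-sequence probes was itself -1.44 log2 lower at 13.5 h.

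The number of changed genes was the first pattern weighed. The real grouping called 7954 genes, and the highest of the other splits of the 6 arrays called 190; that split put the 3 arrays of scan date 2 together. With 10 splits, 1 of which gave as many genes, the share cannot fall below 0.1, so the splits are too few to test chance. For gene lists, 1 of 10 splits gave as many as the real 10, and the highest other gave 7. A difference between scan dates as the whole source is argued against by the blocked fit, which called 10218 genes and still called 98.3% of the 7954. Time of day and time under elevated CO2 stay open as the design's own explanations, untested because both changed together.

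The fall of light harvesting and Calvin cycle genes was the second. Brightest spots were less far above the 75th percentile at 13.5 h (99th percentile 5.23 to 5.36 log2 above it, against 5.73 to 5.78), so a compression of bright spots could lower any bright gene. The slopes that the scanner software fitted to the spike-in controls were 0.874, 0.850 and 0.871 at 7 h. At 13.5 h they were 0.916, 0.914 and 0.861, so the fitted response was not flatter there as a group. These slopes cover the spike-ins and not the bright genes, and the groups overlap, so they do not settle it. The light harvesting median lay at percentile 0.14 of 10000 random lists matched on brightness. The genes drawn were dimmer than the list (median 6.25 against 6.52), so compression stays open. The Calvin cycle median lay at percentile 4.13 and that of the photosystem list at 5.89, within the middle 95% of random lists, as compression would give. The chlorophyll synthesis median lay at percentile 0.16, below that range, and the genes drawn matched the list in brightness (2.72 and 2.72). For that list this argues against compression, though no prediction had been set for it. For the light harvesting and Calvin cycle lists, scan date is argued against by the blocked fit on all 6 arrays, with medians of -0.75 and -0.69. Their medians nearest to 0 within a scan date, with a single array at 1 of the times, were -0.74 and -0.67. Scaling stays open: relative to all genes the medians were -0.18 and -0.18 with quantile normalization, of the same sign but smaller than the -0.77 and -0.62 of the main processing.

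The rise of ribosomal protein genes was the third. The cytosolic and the organelle list both lay at percentile 100 of brightness-matched random lists. Compression would lower bright genes and was no candidate for a rise, so this outcome does not test it. The random lists were drawn gene by gene and lack the correlation between members, so the percentile does not measure chance. Relative to all genes the medians of the cytosolic and the organelle list were 0.49 and 0.70 in the main processing. They were 0.83 and 0.90 with normexp and 0.67 and 0.77 with quantile normalization. Scaling to the median shifts all genes of an array alike, so it cannot test these differences. With scan date as a block the medians themselves were 0.40 and 0.64 (at least 0.28 and 0.47 within a scan date, with a single array at 1 of the times), so neither scaling nor scan date accounts for them alone. The genes of the cytosolic list moved together between arrays of one time (estimated correlation 0.69), so its many members add little independent evidence. A biological difference between the sampling times is a hypothesis that these arrays leave open.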

How the results depend on the processing

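The scan-date subsets, the averaged pair of arrays and the lists without members of other function were chosen after seeing the data. The number of genes called stayed within 1.5 times the main 7954 under all scalings, filters and probe rules. It was 13919 (7287 higher, 6632 lower) with slide as a random block, 3380 (1653, 1727) at an adjusted p under 0.01, 2675 (1335, 1340) for changes beyond 1.5-fold, 5066 (2648, 2418) at 2-fold or more, 3969 (1951, 2018) with the 13.5 h replicates 1 and 2 averaged, 4246 (2148, 2098) in scan date 1 and 12621 (6241, 6380) in scan date 2. The slide block had a consensus correlation of 0.904, and only slides 2 and 4 held more than 1 array. Only slide 2 held both times, so the count with slide as a block carries little weight. With normexp 2521 genes were higher and 5739 lower. Leaving out 1 array gave 3871 to 9250 genes (1913 to 5160 higher, 1958 to 4544 lower); the lowest were without 13.5 h replicate 2 (3871), 13.5 h replicate 1 (3960) and 7 h replicate 2 (4404). The 10 lists called became 5 with normexp, 3 with quantile normalization, 0 with an estimated correlation, 3 with listed loci only (fewer lists tested) and 5 in scan date 2. With normexp the log2 changes of Os02g0744200, Os05g0489800, Os03g0700400 and Os07g0112700 reversed to -0.49, -0.19, -0.14 and -0.15; stricter thresholds lower the count by construction, and the cause was not tested for the rest. Fewer arrays did not by itself lower the count, which rose to 9250 without 7 h replicate 1 and 9147 without 13.5 h replicate 3. The count in scan date 2 rests on the spread of 1 pair of near-identical arrays. With the replicate block 7323 genes and 9 lists were called. Deviations of same-numbered samples correlated at 0.46, -0.31 and 0.26. Over all pairs of a 7 h and a 13.5 h array the sign followed scan date. Pairs within a date gave 0.26 to 0.46, and pairs across dates -0.46 to -0.19. This check therefore cannot tell whether the numbers pair samples. Of the values of named genes under an alternative, 2452 were the same in direction and side of the threshold, 276 weaker, 6 stronger and 4 reversed. Dim probes limit the result: 294 genes were dim on all 7 h arrays and 34 on all 13.5 h arrays. The medians of the random-sequence and genomic probes changed by -1.44 and -1.40 log2 from 7 h to 13.5 h. Falls of genes with 13.5 h arrays not well above background may therefore be overstated.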

Other observations

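Families named by the array's descriptions were tested after the data were seen, 97 families of at least 15 tested genes, with camera at the preset correlation. Of genes described as TPR-like, 137 of 284 were higher and 24 lower at 13.5 h (median 0.69, adjusted p = 5.84e-06, adjusted p = 0.685 with an estimated correlation). The median was 0.69 in scan date 1 and 0.53 in scan date 2, and -0.06 with normexp, where all genes had a median of -0.26. Of genes described as protein prenyltransferase domain proteins, 51 of 119 were higher and 4 lower (median 0.58, adjusted p = 2.11e-05, adjusted p = 0.685 with an estimated correlation). Their median was -0.05 with normexp. These old descriptions were not checked against sequences, so they may not give the genes' function or separate the families. Nonaspanin genes, membrane proteins of the endomembrane system, had 10 of 16 higher and 0 lower (median 0.83, adjusted p = 0.0415, adjusted p = 0.685 with an estimated correlation). Rhodanese-like genes had 9 of 16 lower and 0 higher (median -0.91, adjusted p = 0.0137, adjusted p = 0.685 with an estimated correlation). Of the cytochrome genes described as E-class P450 group I, 9 of 20 were lower and 0 higher (median -0.91, adjusted p = 0.0321, adjusted p = 0.685 with an estimated correlation).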
